A study of Mus musculus with 144 samples.

How the data were processed

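Liver RNA was measured on expression arrays, 1 per library, in 48 groups of 3. Per the labels' protocols, cDNA was primed from poly(A) tails with a T7 promoter, and biotin-labelled RNA copied from it was hybridised. The authors made the values with RMA, whose version and set of arrays are not given, per the submitters' processing notes, and the deposited values are log2 intensities per probe set. That they are log2 was read from the values, which ran from 2.90 to 14.7, with medians of 5.0 to 5.09 per array. No reads or counts lie behind such values, so the number of arrays limits the precision.

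The table held 45101 probe sets. Of these 34945 were used: those with 1 gene symbol in the platform annotation, without control probe sets. For the 34958 probe sets with 1 symbol, controls included, it was looked up by gene ID (34754) or accession (1) or kept from the annotation (203), using a RefSeq table of GRCm38.p6 for names only. For 9010 of 18193 genes with several probe sets the one with the highest mean over the 120 libraries of the 10 younger strains was taken.

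Groups followed the labels: strain, sex and diet, 3 libraries each. The 120 libraries of 10 strains entered 1 fit with 40 cell means and 80 residual degrees of freedom. CAST/EiJ and PERA/Ei (24 libraries) were fitted apart because of their age. Fits used limma 3.58.1 (lmFit, eBayes) in R 4.3.3 with the data.table package (1.17.8), contrasts of cell means, moderated F for comparisons over strains and Benjamini-Hochberg adjusted p under 0.05, with a second count at 2-fold. The contrasts were diet over 10 strains, in each sex and in each strain, sex on each diet, sex by diet, strain on chow, strain by diet and strain by sex on chow. Nothing in the labels says that replicate numbers pair libraries, so no replicate block was used, and a block was tried as an alternative. No scan dates or batches were in the labels.

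Named genes followed a rule: for diet over strains the 15 largest rises and falls among genes past the threshold that moved 1 way in all 10 strain means, for sex on chow the 12 largest each way by the same rule, for sex by diet the 10 largest each way, for strain on chow, strain by diet and strain by sex the 15, 20 and 8 with the largest F, and within each strain the 4 largest each way. Other members of the gene lists were named after their values were seen, preferring large changes. There were 33 lists: cholesterol synthesis and uptake, bile acid synthesis, bile acid sensing and transport, LXR targets, fatty acid synthesis, fatty acid oxidation and PPARA targets, lipid droplet and storage, apolipoproteins, acute phase, chemokines, interferon response, matrix and stellate cells, macrophage, lymphocyte, neutrophil, cholangiocyte, endothelial, hepatocyte, erythroid, pancreas and adipocyte markers, proliferation, cytochrome P450 and flavin monooxygenases, NRF2 targets, male-biased and female-biased genes, ER stress, glucose metabolism, amino acid and urea cycle, oxidative phosphorylation, ribosomal proteins, sex chromosome genes and strain allele checks. List members without a usable probe set were not analysed here. The samples, contrasts, lists, naming rule and most alternatives were fixed before the data were examined.

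Lists were tested with limma's camera with a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the 33 lists of a contrast. Camera compares a list with all other genes, and fry asks whether its members move 1 way. Mean log2 values of a list per library were compared between diets within each strain by an exact permutation of diet within sex (400 arrangements), adjusted over lists and strains, and between strains by limma on the list means.

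The steps were tested on simulated data with the real group layout, with 600 genes changed among 18193. At log2 changes of 0.25, 0.5 and 1 the shares recovered were 98%, 100% and 100% for diet over strains, 95%, 99% and 100% for sex on chow, and 87%, 99.5% and 100% for sex by diet. They were 52%, 93% and 100% for diet within A/J, 35%, 90.5% and 100% for strain by diet, 67.5%, 98% and 100% for strain on chow, 13%, 69.5% and 96.5% for strain by sex, and 39.5%, 88% and 98.5% for CAST/EiJ. False calls were 4.08% to 6.28% of the calls. For lists, 3 of 3 shifted by 0.2 were recovered, with 0 other lists called by camera. The simulated genes varied independently, so this does not test camera on correlated genes. Random splits of the real libraries gave a median of 7 called lists for diet, 6 for sex on chow and 7 for sex by diet.

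Alternatives were a replicate block, eBayes with a trend, array quality weights, quantile normalization, each array centred on its median, all probe sets or their mean, genes above the median gene, adjusted p under 0.01, leaving out each replicate number and each strain, strain as the unit, each strain alone, and fits with CAST/EiJ and PERA/Ei. Fits without the SM/J males, without the 5 libraries of the 10 younger strains farthest from their group mean and without male library 3 of CAST/EiJ on the atherogenic diet were added after the data were seen. Checked were replicate correlations (0.983 to 0.997, 0 identical pairs), labelled sex, and 3' to 5' ratios of control probe sets. The last differed between diets by 0.0048 for Gapdh (permutation p = 0.491) and by -0.04 for Actb (permutation p = 0.00592). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.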

Results

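Liver expression was measured on arrays in 12 inbred mouse strains, with both sexes, 2 diets and 3 libraries in each of 48 groups. The regular chow held 6% fat, and the atherogenic diet held 30% fat with cholic acid, a bile acid that raises fat uptake. Mice of 10 strains were 11 to 13 weeks old at harvest (120 libraries), and CAST/EiJ and PERA/Ei were older than 50 weeks (24 libraries) and were fitted apart. Array medians lay between 5.0 and 5.09 log2 units, and the number of arrays limits the precision. Xist, the RNA that silences an X chromosome, and Eif2s3y, Uty and Kdm5d of the Y chromosome separated the 72 female from the 72 male libraries without overlap. Fas, the death receptor disrupted by the lpr allele, averaged 7.08 on chow in MRL/MpJ-Tnfrsf6lpr/J (SD 0.45, n = 6) and 8.09 or more in the other 9 of the 10 strains. Nnt, a mitochondrial transhydrogenase mutated in C57BL/6J, averaged 9.13 there (SD 0.13, n = 6) and 10.46 or more in the other 9. The diet labels of 2 groups are in doubt: the diet change of the 6 libraries labelled SM/J male correlated negatively across genes with that of the males of the other 9 strains (r = -0.82). They were kept as labelled, and values without them are given beside the counts.

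The first question was how the atherogenic diet changed the liver over the 10 strains. Cholesterol synthesis fell as a whole: all 19 measured members of the cholesterol synthesis and uptake list fell, with a median log2 change of -1.29. Sqle, which makes squalene epoxide, changed by -3.50 (SE 0.09, n = 60 libraries per diet, adjusted p = 3.1e-53), a fall of 11.3-fold. Cyp51 changed by -2.92 (SE 0.07), Idi1 by -2.75 (SE 0.08), Msmo1 by -2.54 (SE 0.07), Fdps by -2.51 (SE 0.09) and Nsdhl by -2.31 (SE 0.06), all enzymes on the route from mevalonate to cholesterol. Hmgcs1 at the head of the route changed by -1.80 (SE 0.07), and Tm7sf2, Dhcr7, Pmvk and Lss by -1.56, -1.54, -1.29 and -1.15. Cyp8b1, the sterol hydroxylase that makes cholic acid, fell 4.03-fold (log2 -2.01, SE 0.08). In the bile acid synthesis list 8 of 12 members fell and 2 rose, among them Cyp7b1 (-0.46) and Cyp27a1 (-0.26) downward, while Cyp7a1, the rate-limiting hydroxylase, did not pass (0.16, SE 0.13). Its camera adjusted p of 0.0379 became 0.296 with an estimated correlation, 0.0625 without replicate 2 and 0.0653 without replicate 3. Of 15 bile acid sensing and transport genes 6 rose and 6 fell, and the list did not pass (adjusted p = 0.671). Nr0b2, the repressor induced by bile acids, rose by 0.43 (SE 0.07), Abcb1a rose by 0.82 and Slco1a1 fell by 0.83.

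Targets of LXR rose, and other lipid genes moved both ways. Of 9 measured targets of this receptor for oxidised sterols, 8 rose, with a median of 0.83. Abcg5 and Abcg8, whose products pump sterols into bile, rose by 1.51 (SE 0.03) and 1.19 (SE 0.04), Abcg1 by 1.34 (SE 0.04) and Srebf1 by 0.97 (SE 0.05). Lpl, which hydrolyses triglycerides of lipoproteins, rose 3.36-fold (log2 1.75, SE 0.06). In the lipid droplet and storage list 7 of 18 rose and 4 fell (9 and 6 adjusted over the list alone), with Apoa4 at 1.01, Cd36 at 0.93, Fabp2 at 0.91 and Fabp4 at 0.90. Its camera adjusted p was 0.00155, or 0.0911 with an estimated correlation. Fatty acid synthesis genes moved both ways (6 rose and 8 fell of 18, adjusted p = 0.594): Scd1 rose by 0.79 (SE 0.06), while Acss2, Acacb and Fads1 fell by 1.00, 0.66 and 0.62. Among 22 fatty acid oxidation genes and targets of PPARA 14 fell and 3 rose (15 and 3 over the list alone). The falls were small except for Cyp4a14 (-0.90, SE 0.14), and the list's adjusted p of 0.0379 became 0.61 with an estimated correlation, 0.0738 with the mean of the probe sets of a gene and 0.463 without replicate 2 (mean -0.03 in place of -0.10). Of 16 apolipoprotein and lipoprotein genes 6 rose and 4 fell (7 and 5 adjusted over the list alone, adjusted p = 0.075). Apoc2 rose by 0.60 and Scarb1 by 0.53, and Apom fell by 0.42.

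Macrophage, matrix and inflammatory genes rose together. Of 20 macrophage markers 19 rose, with a median of 0.97: Lgals3 rose by 2.24 (SE 0.08), Gpnmb by 1.69 (SE 0.07), Lyz2 by 1.30 (SE 0.07) and Cd5l by 1.22 (SE 0.05). The exception was Cd163, the haemoglobin scavenger receptor of resident macrophages, which fell by 1.45 (SE 0.08). Of 19 matrix and stellate cell genes 17 rose and 0 fell with limma (median 0.42), among them Col3a1 (1.29, SE 0.08), Col1a2 (0.91, SE 0.06) and Pdgfrb (0.72, SE 0.05). Another probe set of Sparc (log2 0.52) changed by -0.09. Of 12 endothelial markers 9 rose, mostly by little (median 0.14), Lyve1 by 0.68 and Stab2 by 0.50. Chemokine and inflammatory genes rose in 16 of 21 cases, for example Icam1 (0.85, SE 0.07) and Cxcl10 (0.81, SE 0.11), with an adjusted p of 4.6e-09 that became 0.099 with an estimated correlation. Interferon response genes rose in 16 of 20 cases, for example Gbp2 (1.14, SE 0.12) and Oas1a (0.62, SE 0.05), with 2.0e-08 and 0.226. In the acute phase list 12 of 23 rose and 5 fell (0.000303 and 0.32): the iron-binding protein gene Lcn2 rose by 2.04 (SE 0.15) and Saa3 by 1.55 (SE 0.12), and Hamp, which encodes the iron hormone hepcidin, fell by 0.57 (SE 0.13). Of 11 neutrophil markers 7 rose, S100a8 by 1.14 (0.00569 and 0.245), and of 23 proliferation genes 15 rose and 1 fell (17 and 1 over the list alone, 0.000481 and 0.468), Mcm6 by 0.53.

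**Figure D1:**
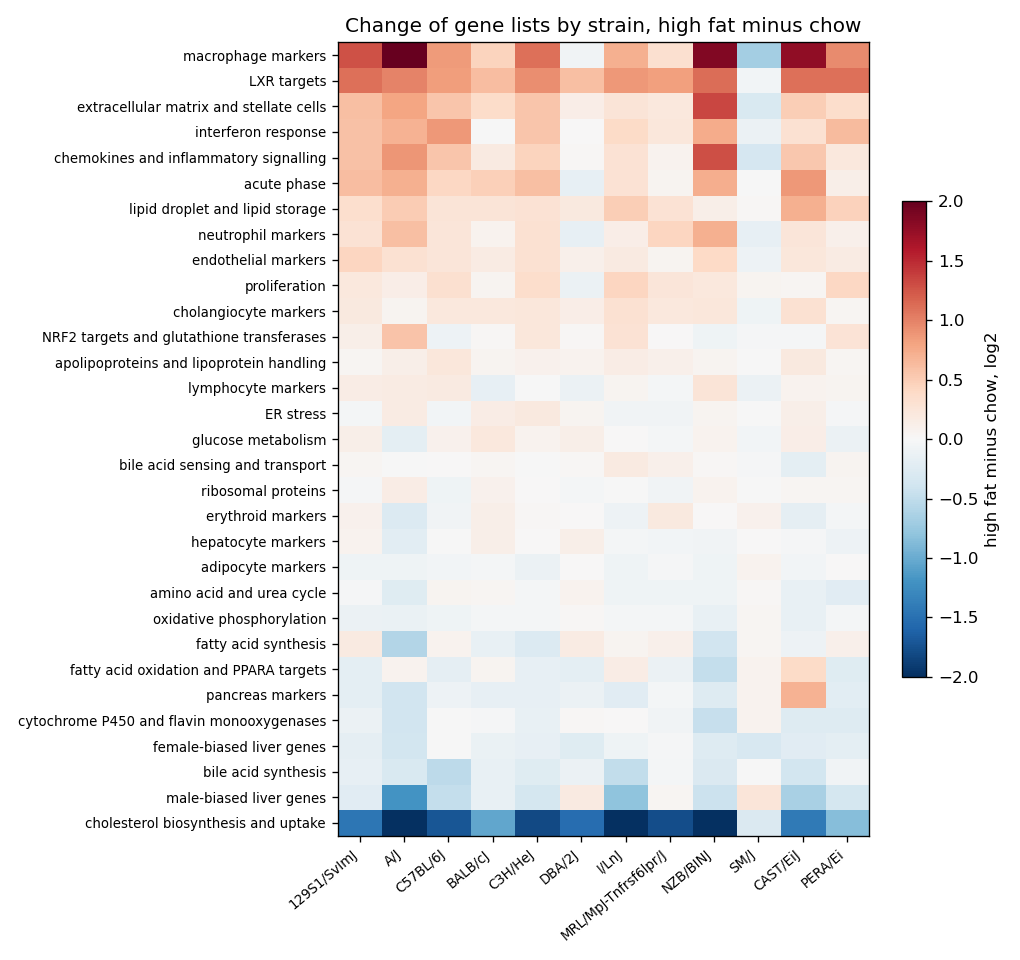
Mean log2 change from chow to the atherogenic diet of 31 gene lists (vertical axis) in each of 12 strains (horizontal axis), 6 libraries per diet and strain, with colour as the change, saturated at 2 and -2. The macrophage list rose by 2.06 in A/J and 1.84 in NZB/BINJ, and the SM/J column mixes both sexes as labelled.

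Male-biased liver genes fell in 10 of 14 cases and rose in 1, with Elovl3 at -1.01 (SE 0.10), and 17 of 24 oxidative phosphorylation genes fell by little (18 over the list alone, median -0.07). Their adjusted p of 0.00064 and 0.000358 became 0.195 and 0.375 with an estimated correlation. Of 17 NRF2 targets and glutathione transferases 8 rose and 3 fell (9 and 3 over the list alone, 0.0472 and 0.505, or 0.0616 without the SM/J males and 0.152 without replicate 2), Hmox1 rising by 0.71, and of 8 pancreas markers 3 fell (6 over the list alone, 0.0379 and 0.375, or 0.12 without replicate 1), Cela1 by 0.89. Cytochrome P450 and flavin monooxygenase genes fell in 11 and rose in 5 of 21 cases (adjusted p = 0.151), with Fmo5 up by 0.73. Female-biased genes fell in 8 and rose in 5 of 18 cases (0.141), and ER stress genes fell in 8 and rose in 5 of 17 (0.816, median -0.06 and mean 0.04). Glucose metabolism (4 rose and 2 fell of 12, 0.149), amino acid and urea cycle genes (4 and 3 of 13, or 4 and 5 over the list alone, 0.674, median 0.003 and mean -0.04), hepatocyte markers (4 and 2 of 16, or 4 and 1, 0.663, tested upward against a mean of -0.01) and lymphocyte markers (4 and 5 of 15, or 5 and 6, 0.736) did not pass. Nor did cholangiocyte (2 and 1 of 9, 0.255, median -0.01 and mean 0.17), erythroid (1 and 1 of 5, 0.851, median -0.05) and adipocyte markers (0 and 2 of 3, 0.447), ribosomal proteins (2 and 2 of 16, 0.674) and sex chromosome genes (0 and 0 of 4, 0.674). The erythroid and ribosomal means were 0.01 each and changed sign with each array centred on its median. Of the strain allele checks Fas, Nnt and Gpnmb all 3 rose, and 1 other probe set of Nnt fell. With the preset correlation 18 of 33 lists passed. With an estimated correlation 6 held: cholesterol synthesis and uptake (0.000202), LXR targets (1.4e-10), macrophage markers (0.0142), matrix (0.00836), endothelial markers (0.0142) and the strain allele checks (0.000579). Of these the strain allele checks share Gpnmb with the macrophage list, and their mean of 0.68 stood against a median of 0.18.

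By count 8461 of 18193 genes passed for diet, 3663 up and 4798 down, and 59 rose and 25 fell by 2-fold or more. Without the SM/J males 8901 passed, of which 8198 were shared, and with strain as the unit (1 value per strain, SM/J males included) 3443 passed. In that setting the calls of Gpnmb (adjusted p = 0.0538), Lyz2, Gbp2, Hmox1, Cxcl10, Hamp, Slco1a1 and Cyp4a14 were lost. The share of called genes that rose was 43.3% as deposited, 39.1% after quantile normalization and 25.5% with each array centred on its median, so the balance of directions depends on the scaling. Among genes with a called probe set 370 of 9934 had called probe sets in both directions. Genes changed in 1 direction in all 10 strain means included Adam11 (1.42, SE 0.04), a protease relative, Wfdc2 (1.02, SE 0.05), the ubiquitin ligase gene Rnf145 (0.91, SE 0.04), Igfbp3 (0.70, SE 0.07), Bst2 (0.68, SE 0.04), Ifi27l2a (0.64, SE 0.08) and 4930459C07Rik (0.72, SE 0.06). The retinol dehydrogenase gene Rdh11 fell by 1.69 (SE 0.07) and the glycolytic gene Aldoc by 1.31 (SE 0.04). The SM/J mean averages both sexes as labelled, so the males in doubt bear on which genes meet this rule. The lowest strain mean was 0.004 for Rnf145 and 0.03 for Igfbp3.

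The next question was whether the sexes responded alike. Across genes the female and male diet changes correlated (Pearson r = 0.849, Spearman rho = 0.664; genes are not independent replicates), with 5911 genes past the threshold in females (3107 up, 2804 down) and 5652 in males (2699 up, 2953 down). Of these 44 rose and 37 fell 2-fold or more in females, and 83 and 22 in males. Without the SM/J males 7423 genes passed in males, of which 5611 were shared. The difference itself passed for 430 genes, 176 with a more positive change in males and 254 with a more positive change in females (8 and 5 at 2-fold). Without the SM/J males 700 passed (365 and 335), of which 334 were shared, and after quantile normalization 401 passed (213 and 188), so the balance of directions is not settled. With strain as the unit limma called 2962 genes in females, 0 in males (4508 at unadjusted p under 0.05) and 0 for the difference (1507 at unadjusted p under 0.05), so these calls hold for the 10 strains studied. The male values included the SM/J males, whose reversed change widens the spread between strains. Strain as the unit was not tried without them, so the 0 in males cannot tell whether the male response is general.

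Several genes that were higher in females fell in females on the atherogenic diet. Of the 18 female-biased genes as a list 9 fell and 4 rose in females (camera adjusted p = 0.000922, or 0.0732 with an estimated correlation). Sult3a1, a sulfotransferase, changed by -2.20 in females, from 11.27 on chow, and by 0.17 in males, from 3.90, a difference of 2.37 (SE 0.18, n = 30 libraries per sex and diet, adjusted p = 3.1e-18). The differences were 1.38 for Cyp3a16, 1.23 for Hao2 and 1.18 for the transporter gene Slc22a26, whose male changes were 0.00, 0.04 and -0.07. Male chow values of Sult3a1, Cyp3a16 (3.29), Hao2 (4.78) and Eci3 (4.43) lay below the median array value of 5.04, where a fall can hardly be read, so for these genes the difference gives the female change alone. Mup10, a urinary pheromone carrier, differed by 1.84 and fell in both sexes (-2.39 and -0.56), as did Dct (1.13). Eci3 differed by 0.98, 9030619P08Rik by 1.03, the lipocalin gene Obp2a by 0.91 and Mt2, a metallothionein, by 1.04 (SE 0.28, adjusted p = 0.0247). In the other direction Cyp4a14, a fatty acid hydroxylase induced by PPARA, fell by 1.86 in males and changed by 0.05 in females, a difference of -1.90 (SE 0.28). Lepr, the leptin receptor, rose by 1.59 in females and by 0.28 in males (difference -1.31, SE 0.15), and Nox4 and the heat shock gene Hspb1 differed by -0.96 and -1.01. Csad, Dnase2a, Cyp2c55, Ppp1r3g, Lpin1 and the oestrogen sulfotransferase gene Sult1e1 differed by -1.27, -1.02, -0.88, -0.81, -0.73 and -0.69. Some of these calls hung on 1 replicate number or 1 strain. Lpin1 did not pass without 129S1/SvImJ (-0.38) or replicate 3, Obp2a without C3H/HeJ (0.58) or replicate 2, and Ppp1r3g without BALB/cJ (-0.53), 129S1/SvImJ, C3H/HeJ or any 1 replicate. Nor did Mt2 without replicate 2 (0.64), replicate 1, A/J, C57BL/6J or C3H/HeJ, and Cyp2c55 without replicate 2 (-0.56) or C3H/HeJ. The same held for Sult1e1 without replicate 2 (-0.50), Cyp3a16 without replicate 3 (1.02) and Nox4 without replicate 1 (-0.73) or 3. A call can also go because 2 libraries per group remain. Without replicate 3 Ppp1r3g differed by -1.01 and without replicate 1 Mt2 by 1.18, more than with all libraries.

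**Figure D2:**
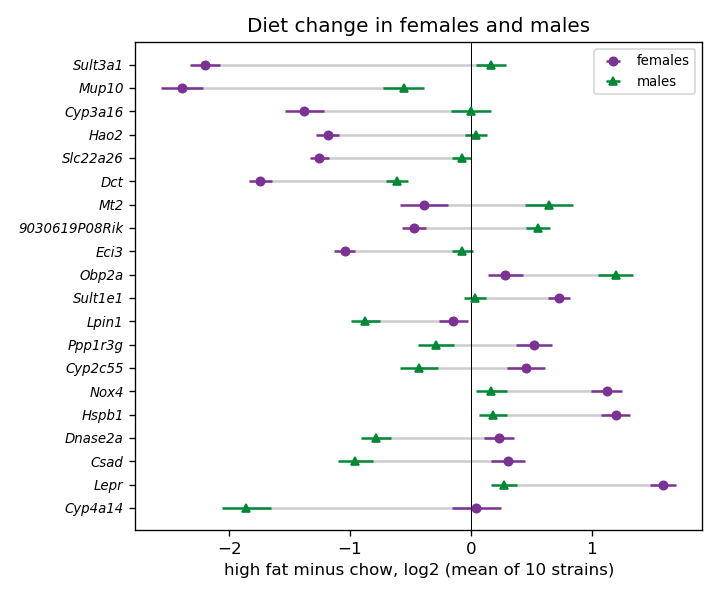
Log2 change from chow to the atherogenic diet (horizontal axis, mean of 10 strains) of the 20 named genes of the sex by diet comparison, females and males as separate points with bars for the SE. Sult3a1 changed by -2.20 in females and 0.17 in males, and Cyp4a14 by 0.05 and -1.86.

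By list, 20 of 33 passed for sex by diet with the preset correlation and 2 with an estimated one: female-biased genes (6 of 18 more positive in males and 1 in females, 11 and 2 over the list alone, median 0.32, 0.000504) and lymphocyte markers (3 and 0 of 15, 4 and 0 over the list alone, 0.022), with Ighm at 0.39. That of Ighm was 0.03 with the mean of its probe sets (adjusted p = 0.877) and 0.20 without C57BL/6J (adjusted p = 0.319). On the female-biased list, male chow means of Sult3a1 (3.90), Cyp3a16 (3.29) and Hao2 (4.78) lay below the median array value of 5.04. A fall in males can hardly be read there, so part of this list's difference may reflect that limit. Ribosomal proteins were more positive in females in 6 of 16 cases (14 over the list alone, median -0.09), with an adjusted p of 6.7e-13 that became 0.0749. As labelled, the lists below passed by camera only with the preset correlation, whose adjusted p is given first and that with an estimated correlation second. By fry 8 lists passed: the 3 above, LXR targets (0.0136), ER stress (0.0143), acute phase genes (0.0143), lipid droplet (0.0299) and cytochrome P450 genes (0.0496). More positive in males were acute phase genes (1.6e-08 and 0.165), cholesterol synthesis (7.3e-08 and 0.253), macrophage markers (2.0e-07 and 0.253), interferon response (5.8e-05 and 0.367), cytochrome P450 genes (0.0023 and 0.253), chemokines (0.0072 and 0.41), proliferation (0.0254 and 0.571), neutrophil and pancreas markers (each 0.0315 and 0.367) and matrix (0.0459 and 0.521). More positive in females were fatty acid oxidation (1.8e-05 and 0.363), oxidative phosphorylation (0.00229 and 0.384), ER stress (0.00864 and 0.247), lipid droplet (0.0252 and 0.253), LXR targets (0.0315 and 0.247), endothelial markers (0.0315 and 0.31) and glucose metabolism (0.0418 and 0.365). Without the SM/J males the means of the cholesterol, LXR and endothelial lists changed sign (-0.04, 0.11 and 0.0003), and 14 of 20 macrophage markers were more positive in males in place of 2. In that fit acute phase genes (0.0142) and macrophage markers (0.0162) passed with an estimated correlation also. The cholesterol (0.804), endothelial (0.848), ER stress (0.115), lipid droplet (0.265), glucose (0.265) and pancreas lists (0.216) lost their call with the preset one, and fatty acid synthesis gained one (0.0355). Leaving out 1 or more of the replicate numbers in turn ended the call of 11 lists, each given here for 1 of them. Without replicate 1 the LXR (0.113), endothelial (0.394), ER stress (0.0768), matrix (0.115), glucose (0.155), lipid droplet (0.112), proliferation (0.112) and pancreas lists (0.535) did not pass. Neither did the neutrophil (0.223) and oxidative phosphorylation lists (0.342) without replicate 2, and cytochrome P450 genes (0.116) without replicate 3. The other 13 lists did not pass, with adjusted p from 0.0641 (NRF2 targets) to 0.865 (hepatocyte markers). Among these the means of apolipoproteins and of adipocyte markers changed sign with the scaling, and male-biased genes had a median of -0.08, a mean of 0.03 and an upward test.

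Sex itself set large differences on chow. Male-high genes were Cyp4a12a (7.25, SE 0.12, n = 30 libraries per sex), a hydroxylase under androgen control, Hsd3b5 (5.32, SE 0.20), Elovl3 (4.56, SE 0.14), Nox4 (3.15, SE 0.13), C6 (3.06, SE 0.08), Serpina4-ps1 (2.78, SE 0.22), Cyp2d9 (2.61, SE 0.06), Cyp7b1 (2.59, SE 0.08), Slco1a1 (2.51, SE 0.18) and Scara5 (2.46, SE 0.10), and Eif2s3y (5.31) and Kdm5d (2.53) of the Y chromosome. Female-high genes were the sulfotransferase genes Sult3a1 (-7.37, SE 0.13) and Sult2a2 (-7.25, SE 0.13), Xist (-6.49), Hao2 (-6.04, SE 0.09), the organic anion transporter genes Slc22a26, Slc22a27 and Slc22a29 (-4.51, -3.57 and -3.35), Cyp3a16 (-3.94), Cyp2c39 (-3.55), Acot3 (-3.39), Nt5e (-3.26) and 9030619P08Rik (-3.13). The lower sex lay below the median array value of 5.04 for Cyp4a12a, Scara5, Eif2s3y, Kdm5d, Sult3a1, Sult2a2, Xist, Hao2, Slc22a27, Slc22a29 and Cyp3a16, so the sizes of these differences are lower bounds. In all 5201 genes differed on chow, 2847 higher in males and 2354 higher in females, with 46 and 68 at 2-fold. On the atherogenic diet 4454 differed, 2104 and 2350, with 49 and 54 at 2-fold. The balance depended on the scaling: with each array centred on its median 3633 and 2050 passed on chow, and after quantile normalization 2213 and 2194 on the atherogenic diet. Without the SM/J males the counts were 5322 (4604 shared) and 3844 (3673 shared).

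Of 33 lists 20 passed for sex on chow, and 6 held with an estimated correlation. All 14 male-biased genes were higher in males (median 1.87, 5.1e-11), and 16 of 18 female-biased genes were higher in females (median -2.12, 8.0e-15). Cytochrome P450 genes were higher in males in 6 and in females in 9 of 21 cases (10 in females over the list alone, 0.0113), with Cyp2b9 at -5.65 and Cyp2b13 at -5.36. Bile acid sensing and transport genes were higher in females in 9 and in males in 2 of 15 cases (0.0116), for example Slco1a4 (-1.97) and Abcb1a (-1.30). Sex chromosome genes (0.000701) and the strain allele checks (0.0239) also held. The other 14 lists lost their call with an estimated correlation. Higher in females were acute phase genes (1.3e-05 and 0.198), apolipoproteins (3.9e-05 and 0.0509), interferon response (5.4e-05 and 0.363), cholesterol synthesis and macrophage markers (each 0.00135 and 0.381), fatty acid oxidation (0.00187 and 0.381), amino acid and urea cycle genes (0.00389 and 0.325), endothelial markers (0.0116 and 0.198) and proliferation (0.0225 and 0.551). Higher in males were ribosomal proteins (0.00502 and 0.381), bile acid synthesis (0.00904 and 0.186), oxidative phosphorylation (0.00904 and 0.424), erythroid markers (0.0107 and 0.113, through Alas2 at 2.35) and NRF2 targets (0.0169 and 0.381). Without replicate 2 the endothelial (0.0794), bile acid synthesis (0.0564) and NRF2 lists (0.0972) did not pass. The other 13 lists had adjusted p from 0.0579 (glucose metabolism) to 0.987 (chemokines). The fit without the SM/J males ended the call of the cholesterol list (0.502, median 0.03) and added LXR targets (0.00159, median -0.24), matrix (0.00579) and lymphocyte markers (0.0487). With an estimated correlation LXR targets (0.0165), acute phase genes (0.0343) and apolipoproteins (0.0497) then passed also. Among the lists that did not pass as labelled the means of adipocyte and hepatocyte markers changed sign with the scaling. Cholangiocyte markers had a median of 0.02, a mean of -0.04 and an upward test, and chemokines a median and mean of 0.01 and a downward test.

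Several of the 15 genes with the largest strain F on chow stood apart in 1 or a few strains. Stard10, a phospholipid carrier, averaged 5.33 in I/LnJ and 12.1 or more in the other 9 strains (F = 2341, within-group SD 0.11, n = 6 libraries per strain). Hsd17b13, a lipid droplet enzyme, averaged 7.05 in C3H/HeJ and 11.59 or more elsewhere, and Wfdc21 8.07 in NZB/BINJ and 12.58 or more elsewhere. Akr1c18, a hydroxysteroid dehydrogenase, was high in NZB/BINJ alone (9.82, next 5.95), where Akr1c12 was low (7.62, next 9.84), and Akr1a1 was low in I/LnJ (11.0, next 12.8), which its second probe set did not follow (r = -0.174 over the 10 strain means). The class I histocompatibility gene H2-D1 was low in C3H/HeJ and MRL/MpJ-Tnfrsf6lpr/J (8.30 and 8.33), Reep3 in I/LnJ and SM/J (5.11 and 5.65), Abhd1 in DBA/2J and C57BL/6J (5.72 and 6.28), and Pdxdc1 in DBA/2J, BALB/cJ and C3H/HeJ (6.04, 6.10 and 6.22). High in few strains were Gm7969 (C57BL/6J, 7.88), Trim34a (SM/J and C57BL/6J, 7.78 and 7.69), Nlrp12 (C57BL/6J and A/J, 10.3 and 9.79), Corin (I/LnJ, DBA/2J and C3H/HeJ, up to 6.63) and Cox6b2 (MRL/MpJ-Tnfrsf6lpr/J, BALB/cJ, 129S1/SvImJ and NZB/BINJ, up to 9.13). By moderated F 8921 genes differed, and 8458 without the SM/J males (8294 shared). A probe set can read low because a strain's sequence differs under its probes, which 216 of 291 genes with strain means at least 2 log2 units apart could not be checked for. Of the 15 genes named here only 4 had a second bright probe set. Besides Akr1a1 these were Reep3, H2-D1 and Pdxdc1, where the strain means of both correlated at 0.89, 0.999 and 0.992. Such agreement does not exclude a variant that both probe sets cover, since probe sequences were not used.

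Several macrophage genes were among the 20 with the largest strain by diet F. Gpnmb, a glycoprotein of lipid-loaded macrophages, rose by 5.70 in NZB/BINJ and 4.61 in A/J (SE 0.22, 6 libraries per diet) and changed by -0.09 in DBA/2J (F = 81.7). It is also one of the strain allele checks, so an allele may bear on its flat value in a strain, which was not tested. In C3H/HeJ the mean of Gpnmb went from 5.33 to 5.98 in females and from 5.48 to 9.19 in males. Mmp12, a macrophage elastase, rose by 5.11 in NZB/BINJ and 4.83 in A/J, and Lgals3, Clec7a, Capg, Cd68, Itgax, Lyz1, Lyz2 and Abcg1 had their top changes in the same 2 strains (F from 34.0 to 45.3). So did Rragd (F = 72.5), Pla2g2d (60.2), Gpr137b (49.0), Gpr137b-ps (41.6), Scd2 (44.55), Kcnj10 (35.3) and Anxa1 (33.7). Akr1c18 fell in NZB/BINJ by 1.91 (F = 50.9), Afm, a vitamin E carrier, in A/J by 1.14 (F = 34.7), and Cd207 rose in A/J by 3.04 with -1.23 in MRL/MpJ-Tnfrsf6lpr/J (F = 44.0). Akr1c18 was high on chow in NZB/BINJ alone (9.82, next 5.95), so the other strains had far less signal to lose. F fell to 20.1 for Scd2, 20.5 for Abcg1 and 29.1 for Lgals3 (from 44.55, 41.0 and 44.4) without the SM/J males. By moderated F 4933 genes passed, and 3743 without the SM/J males (3687 shared).

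**Figure D3:**
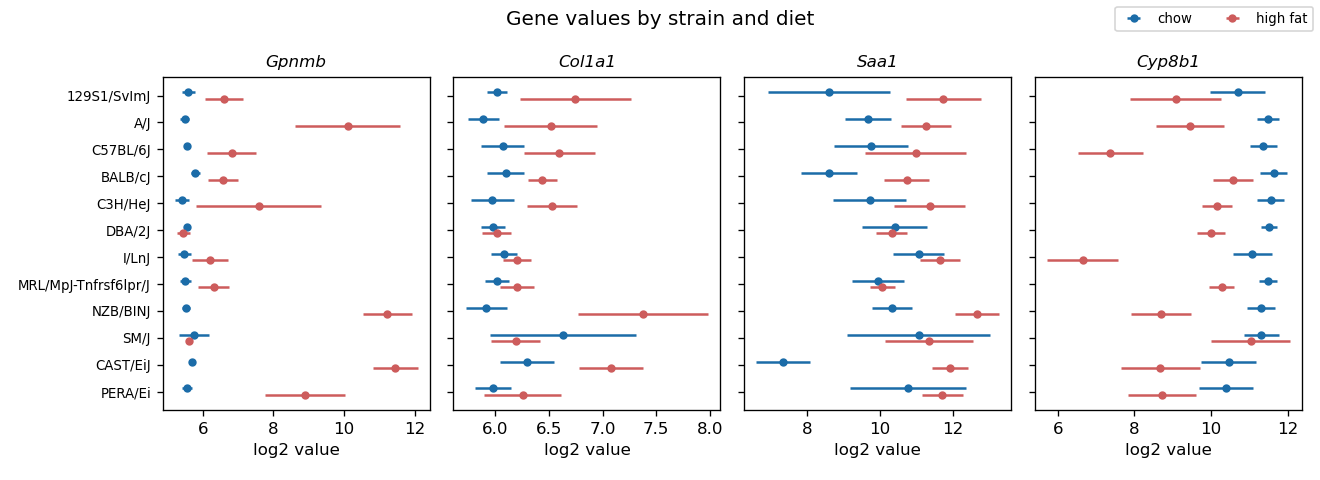
Mean log2 values of Gpnmb, Col1a1, Saa1 and Cyp8b1 (horizontal axes) on chow and on the atherogenic diet in each strain (vertical axis), with bars for the SD of 6 libraries. Gpnmb, also one of the strain allele checks, rose by 5.70 in NZB/BINJ and 4.61 in A/J and changed by -0.09 in DBA/2J.

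List means per strain showed which strains moved. The macrophage list rose by 2.06 in A/J, 1.84 in NZB/BINJ, 1.27 in 129S1/SvImJ, 1.11 in C3H/HeJ, 0.86 in C57BL/6J, 0.72 in I/LnJ and 0.44 in BALB/cJ (each exact permutation p = 0.005, the smallest that 400 permutations allow, two-sided, adjusted 0.0174). It rose by 0.33 in MRL/MpJ-Tnfrsf6lpr/J and did not pass in DBA/2J (-0.07, exact permutation p = 0.375). These values average the sexes, and in females and males they were 0.50 and 2.04 in 129S1/SvImJ, 0.62 and 1.59 in C3H/HeJ and 0.27 and 1.44 in C57BL/6J, a difference not tested within strains. The matrix list rose by 1.34 in NZB/BINJ, 0.78 in A/J and 0.60 in 129S1/SvImJ, and did not pass in DBA/2J (0.13, adjusted exact permutation p = 0.0797). The chemokine list rose by 1.30 in NZB/BINJ and 0.88 in A/J, and the interferon list by 0.87 in C57BL/6J. Cholesterol synthesis fell in 9 strains, by 1.04 in BALB/cJ to 2.45 in A/J, and LXR targets rose in the same 9, by 0.60 in DBA/2J to 1.12 in NZB/BINJ. The strain by diet F on list means passed for 26 of 33 lists, among them the strain allele checks (69.9), LXR targets (51.9, or 13.2 without the SM/J males), macrophage markers (28.2, or 22.5), matrix (22.3, or 15.9) and cholesterol synthesis (14.8, or 5.86). The strain allele checks held only 3 genes. Gpnmb among them had the largest F of single genes (81.7) and is also on the macrophage list. Over the 9 strains without SM/J the macrophage change was related to that of 6 other lists, a family chosen after the values were seen. For chemokines r was 0.923 and rho 0.967 (permutation p = 1e-04, adjusted 0.0006, r = 0.954 without A/J and DBA/2J, the 2 strains farthest from the mean). For matrix r was 0.863 and rho 0.95 (permutation p = 0.00075, adjusted 0.00225, 0.922 without them), for acute phase 0.888 and 0.933 (0.00165, 0.0033, 0.838), for LXR targets 0.852 and 0.917 (0.00455, 0.00682, 0.865) and for interferon 0.782 and 0.767 (0.0145, 0.0175, 0.707). The relation with cholesterol synthesis did not pass (r = -0.648, rho = -0.567, permutation p = 0.0591, -0.409 without them).

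**Figure D4:**
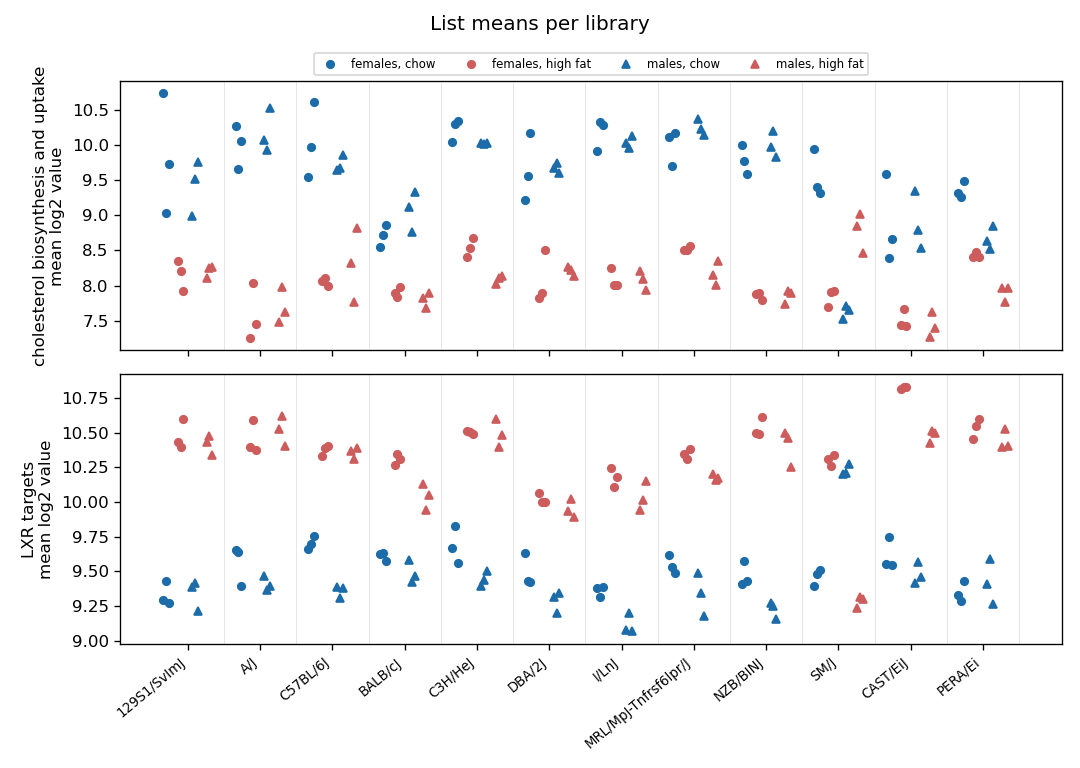
Mean log2 value of the cholesterol synthesis and LXR lists (vertical axes) in each library by strain (horizontal axis), with circles for females, triangles for males and colour for the diet as labelled. The cholesterol list changed by -1.72 in SM/J females and by 1.15 in the libraries labelled SM/J male.

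Within strains the counts ran from 94 to 6188 genes. A/J had 6188 (2836 up, 3352 down), led by Mmp12 (28.5-fold, SE 0.26 in log2, 6 libraries per diet), Ubd (27.1-fold), a ubiquitin-like protein gene induced by cytokines, Lgals3 (24.9-fold) and Gpnmb (24.4-fold), with Mup10 down 14.6-fold. NZB/BINJ had 4992 (2590 up, 2402 down), with Gpnmb up 51.9-fold, Mmp12 34.5-fold, Clec4e 23.4-fold and Ubd 21.7-fold, Cd163 down 19.8-fold and Cyp4a14 9.24-fold. C57BL/6J had 2003 (1099 up, 904 down), with the early response genes Fos (7.22-fold) and Jun (5.13-fold), Apoa4 (4.71-fold) and Lgals3 (4.59-fold) up and Cyp8b1 down 16.0-fold. In 129S1/SvImJ 1947 passed (1271 up, 676 down), with Saa3 (10.7-fold), Saa2, Saa1 and Cxcl9 up and Serpina4-ps1 down 4.82-fold. I/LnJ had 1873 (1150 up, 723 down), with Ptgds (7.68-fold), a prostaglandin synthase, Lpl (5.94-fold), Lcn2 and Spink1 up and Cyp8b1 down 21.4-fold. C3H/HeJ had 1623 (1093 up, 530 down), with Mmp12 (11.6-fold), Lgals3, Clec7a and Lcn2 up. BALB/cJ had 966 (632 up, 334 down), with Lcn2 (5.66-fold), Saa1, Mmp12 and Lgals3 up and Tcf24 down 3.98-fold, and MRL/MpJ-Tnfrsf6lpr/J had 911 (514 up, 397 down), with Mmp12 (6.84-fold), the circadian gene Dbp (5.19-fold), Abcg5 and Wfdc2 up. DBA/2J had 389 (265 up, 124 down), with Obp2a (6.49-fold), Fos, Alas1 and Gadd45g up. In DBA/2J Fos did not pass without replicate 2 (log2 1.75) or 3 (1.42), nor Gadd45g without replicate 3 (1.03, adjusted p = 0.407). The same held for Lcn2 in BALB/cJ without replicate 1 (2.10) and in I/LnJ without replicate 3 (1.62), and for Serpina4-ps1 in 129S1/SvImJ without replicate 2 (-1.76). At 2-fold the counts up and down were 473 and 109 in A/J, 527 and 73 in NZB/BINJ, 123 and 34 in C57BL/6J, 156 and 40 in 129S1/SvImJ, 88 and 56 in I/LnJ, 127 and 43 in C3H/HeJ, 44 and 25 in BALB/cJ, 32 and 39 in MRL/MpJ-Tnfrsf6lpr/J and 25 and 23 in DBA/2J. The largest falls in these 9 strains were otherwise sterol genes, with Sqle down from 8.94-fold in 129S1/SvImJ to 26.4-fold in I/LnJ in the 8 strains that name it.

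**Figure D5:**
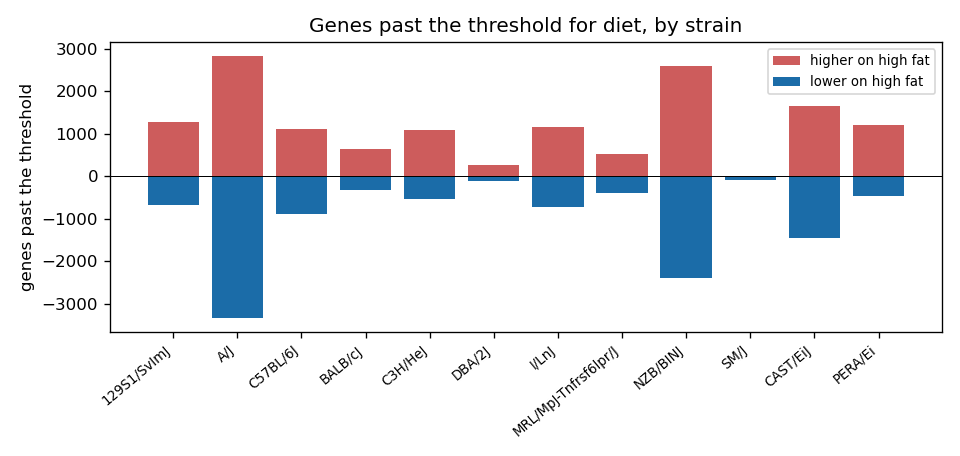
Genes past the threshold for diet in each strain (vertical axis, rises above 0 and falls below it), 6 libraries per diet and strain. In the 10 younger strains totals ran from 94 in SM/J, where the labels of the males are in doubt, to 6188 in A/J.

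In SM/J the 2 sexes moved apart. The cholesterol list changed by -1.72 in females and by 1.15 in the libraries labelled male (difference 2.87, SE 0.31, adjusted p = 5.0e-13), and the LXR list by 0.84 and -0.94. With both sexes as labelled 94 genes passed (12 up, 82 down, 1 and 18 at 2-fold), with Moxd1 (2.00-fold), Slc3a1, Fads1 and Albfm1 up and Ubd, Lyz2 (3.33-fold), Lyz1 and Marco down. None of these 8 passed with SM/J fitted alone. In the females alone 268 passed (126 up, 142 down), of which 20 were shared, and Lyz2 and Lyz1 changed by 1.33 and 1.18, Fads1 by -1.10 and Moxd1 by -0.02. The values over strains that name SM/J carry this doubt.

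The sex difference on chow itself varied between strains. Cyp2b13 and Cyp2b9, female hydroxylases of drugs and steroids, differed by -3.63 to -7.12 and by -1.16 to -8.13 in 9 strains and by 0.07 and 0.31 in 129S1/SvImJ (F = 85.0 and 49.8). Sult3a1 was female-high in 9 strains (-7.22 to -8.89) and not in BALB/cJ (-0.25, F = 41.7), and Sult2a2 not in I/LnJ (-0.59, F = 37.3). Mean male values of both lay below the median array value, so the sizes of the female-high differences are lower bounds. Cyp2b13, Cyp2b9, Sult3a1, Sult2a2, Rdh16f2 and Myom2 had no second bright probe set. A variant under the probes could lower both sexes of a strain, so it cannot be told apart here from a missing sex difference. Rdh16f2 ranged from -0.70 in A/J to -5.53 in SM/J (F = 49.4, or 20.4 without the SM/J males), Myom2, a muscle protein gene, from -0.18 in SM/J to 3.83 in NZB/BINJ (F = 35.8), and Cyp2d9 from 1.13 in I/LnJ to 4.47 in MRL/MpJ-Tnfrsf6lpr/J (F = 27.5). Lyz1 passed through SM/J alone (4.23, F = 29.7), and without the SM/J males its adjusted p was 0.182. By moderated F 2609 genes passed, and 1085 without the SM/J males, all 1085 shared.

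CAST/EiJ and PERA/Ei, the older strains, had 3100 genes (1649 up, 1451 down, 247 and 66 at 2-fold) and 1671 genes (1212 up, 459 down, 134 and 35 at 2-fold) past the threshold. In CAST/EiJ Gpnmb rose 53.7-fold (log2 5.75, SE 0.27, 6 libraries per diet), Lgals3 44.7-fold, Saa1 23.9-fold and Lyz1 18.2-fold. Cd163 fell 8.64-fold, Msmo1 7.18-fold, Cxcl13, a B cell chemokine, 6.53-fold and Sqle 6.42-fold. In PERA/Ei Mmp12 rose 15.9-fold (log2 3.99, SE 0.20), Gpnmb 10.1-fold, Clec7a 9.37-fold and Lpl 8.01-fold, while Cd163 fell 7.16-fold, Pcp4l1 3.79-fold, Cyp2b10 3.56-fold and Cyp4a14 3.24-fold (not past the threshold without replicate 1). Male library 3 of CAST/EiJ on the atherogenic diet carried pancreas markers (list mean 10.4 against 5.25 to 5.59 in the other 11). Without it 2693 genes passed in CAST/EiJ and 1660 in PERA/Ei. Age and strain cannot be separated in these 2 strains.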

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

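Chosen only after their results were seen were the test of exchanged diet labels, the test of the hepatocyte share, all counts of splits and the fits without the SM/J males and without the 5 farthest libraries. The comparisons of strains and sexes themselves were set before the data were examined.

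The first pattern was the reversed diet response of SM/J males: the cholesterol list differed between the libraries labelled SM/J male and the females by 2.87, and across genes the male change had r = -0.82 with the males of the other 9 strains, whose own values ran from 0.23 to 0.845. Libraries of another strain were argued against, since 5 of 6 lay nearest to SM/J females, with labelled chow library 3 nearer to NZB/BINJ (r = 0.295) than to the next strain (0.281). Exchanged diet labels are a candidate explanation: the LXR list lay on the side of the other diet in 6 of 6 libraries and the cholesterol list in 5 of 6, and the size of the change (0.303) was within the range of the other strains (0.199 to 0.456). Labelled high-fat library 3 stayed on its own side of the midpoint by 0.24, less than the SD of 1 library (0.27), an allowance that was added after this library had been seen and without which the test would have counted against an exchange. A response of SM/J males that is truly opposite stays open, as untested.

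The second pattern was the macrophage response of A/J and NZB/BINJ. A lower share of hepatocytes would raise all other cell types alike, but the macrophage list rose by at least 1.45 more than the cholangiocyte, endothelial and lymphocyte lists in both strains. The matrix list, which was not weighed, rose by 0.78 in A/J and by 1.34 in NZB/BINJ, there 0.503 less than the macrophage list. Single libraries were argued against. Without the 5 farthest libraries of the younger strains the macrophage list still rose by 2.27 in A/J and 1.97 in NZB/BINJ. With arrays centred on their medians it rose by 2.02 and 1.78. The array medians differed too little for centring to remove such rises. Centring therefore cannot decide on the authors' normalization, which stays open. A strain difference in macrophage recruitment or activation may explain the macrophage response, as a hypothesis on the same data.

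The third pattern was the size of strain differences on chow. A variant under the probes of only 1 probe set would make the probe sets of a gene disagree. Over 75 genes with a second bright probe set the strain means of both had a median r of 0.983 (quartiles 0.90 and 0.996), with 5 genes below 0.3, among them Akr1a1 (-0.174). For most of these genes this argues against a variant under 1 probe set alone. A variant that both probe sets cover cannot be excluded, since probe sequences were not used. For the 216 genes without a second bright probe set a variant and a difference in RNA cannot be told apart, because no second probe set reads them. Part of the named strain differences may therefore be sequence variants.

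Splits of the libraries tested whether a regrouping gives a count as large as the real one. All strains of a fit were regrouped at once. Real changes could then widen the spread within groups and lower the other counts. The test therefore cannot exclude chance for a single strain. Each comparison had 100 splits, and in 1 of them, the real one, the count was as large, except for the lists of sex on chow with 2. Over strains this test argued against chance for diet (8461 genes, highest other split 11), females (5911, 1457), males (5652, 30), sex on chow (5201, 171) and on high fat (4454, 16), sex by diet (430, 6), strain on chow (8921, 9), strain by diet (4933, 2) and strain by sex (2609, 31). Within strains the real count was also the largest, for 129S1/SvImJ (1947, 114), A/J (6188, 1971), C57BL/6J (2003, 104), BALB/cJ (966, 175), C3H/HeJ (1623, 72), DBA/2J (389, 36), I/LnJ (1873, 44), MRL/MpJ-Tnfrsf6lpr/J (911, 128), NZB/BINJ (4992, 4046), SM/J (94, 70), CAST/EiJ (3100, 2772) and PERA/Ei (1671, 50). In SM/J, where the sexes moved apart, the count ran from 6 to 348 without 1 replicate in turn. For the lists the real counts were 18 for diet (highest other 16), 20 for sex on chow (22) and 20 for sex by diet (15). The medians of the other splits were 7, 6 and 7 lists, so camera with the preset correlation calls several lists without a real grouping. The source of the high counts of single other splits in females, A/J, NZB/BINJ, SM/J and CAST/EiJ was not tested.

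Genes stood out because the test of a difference between groups passed. For sex by diet (430 genes) the male minus female values were 2.37 for Sult3a1, 1.84 for Mup10, 1.38 for Cyp3a16, 1.23 for Hao2, 1.18 for Slc22a26, 1.13 for Dct, 1.04 for Mt2, 1.03 for 9030619P08Rik, 0.98 for Eci3 and 0.91 for Obp2a. On the other side were Cyp4a14 (-1.90), Lepr (-1.31), Csad (-1.27), Dnase2a (-1.02), Hspb1 (-1.01), Nox4 (-0.96), Cyp2c55 (-0.88), Ppp1r3g (-0.81), Lpin1 (-0.73) and Sult1e1 (-0.69). For strain by diet (4933 genes) F was 81.7 for Gpnmb, 72.5 for Rragd, 60.2 for Pla2g2d, 50.9 for Akr1c18, 49.0 for Gpr137b, 45.3 for Lyz2, 45.0 for Mmp12, 44.55 for Scd2, 44.4 for Lgals3, 44.0 for Cd207, 41.6 for Gpr137b-ps, 41.0 for Abcg1, 39.9 for both Lyz1 and Clec7a, 36.9 for Capg, 36.8 for Cd68, 35.3 for Kcnj10, 34.7 for Afm, 34.0 for Itgax and 33.7 for Anxa1. For strain by sex (2609 genes) it was 85.0 for Cyp2b13, 49.8 for Cyp2b9, 49.4 for Rdh16f2, 41.7 for Sult3a1, 37.3 for Sult2a2, 35.8 for Myom2, 29.7 for Lyz1 and 27.5 for Cyp2d9.

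List means stood out for the same reason. The strain allele checks, only 3 genes, share Gpnmb with the macrophage list. The strain by diet F passed for 26 of 33: strain allele checks (69.9), LXR targets (51.9), macrophage (28.2), matrix (22.3), cholesterol synthesis (14.8), chemokines (12.5), male-biased genes (12.1), endothelial (11.7), neutrophil (11.4), lipid droplet (9.85), bile acid synthesis (8.18), cytochrome P450 (7.10), lymphocyte (6.82), acute phase (5.80), NRF2 targets (5.65), cholangiocyte (5.37), erythroid (5.23), pancreas (4.99), ER stress (4.61), interferon (4.14), oxidative phosphorylation (3.87), ribosomal proteins (3.85), fatty acid synthesis (3.58), hepatocyte (2.94), apolipoproteins (2.86) and fatty acid oxidation (2.85). The sex by diet difference of list means passed for 13: female-biased genes (0.43), acute phase (0.29), cholesterol synthesis (0.25), macrophage (0.25), cytochrome P450 (0.15), lymphocyte (0.14), LXR targets (-0.082), endothelial (-0.0715), lipid droplet (-0.0851), ribosomal proteins (-0.10), erythroid (-0.11), ER stress (-0.11) and fatty acid oxidation (-0.23). By camera 20 lists passed for sex by diet. The cholesterol, LXR and endothelial differences changed sign without the SM/J males. Some female-biased genes lay near the background in males, where a fall can hardly be read, which limits the female-biased difference.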

How the results depend on the processing

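The fits without the SM/J males, without the 5 farthest libraries and without 1 CAST/EiJ library, and the list tests without a replicate, were chosen only after results were seen. The other alternatives were fixed beforehand.

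Of 26 counts under 415 alternatives, 323 stayed within 1.5 times and 92 moved further. Of 329 named genes and lists under 5806 alternatives, 5590 kept their direction and side of the threshold, 209 kept the direction but passed no longer, and 7 reversed. No named gene lost its call under eBayes with a trend, array weights, quantile normalization, centring or the replicate block. Of the lost calls, 44 were lists with an estimated correlation, 13 were lists under fry and 29 were genes with strain as the unit. Array signal limits genes near the background, where the median array value was 5.04, and 3 libraries per group limit single strains. The exact permutation of list means within a strain was not run without a replicate, since the fewer arrangements cannot reach the threshold. Unless said otherwise the cause of a change was not tested.

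Replicate numbers shared nothing measurable: deviations correlated by 0.000582 on average with the same number and by -0.000296 with different ones, and 24.4% of same-number pairs exceeded 0.1. With the replicate block 8462 genes passed for diet in place of 8461 (8432 shared) and 439 for sex by diet in place of 430 (426 shared).

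Without 1 replicate in turn, which leaves 2 libraries per group, counts ran from 5732 to 7225 for diet (8461 with all), 3978 to 4990 in females (5911), 3857 to 4283 in males (5652), 165 to 189 for sex by diet (430), 3616 to 4040 for sex on chow (5201) and 3104 to 3521 on high fat (4454). Within strains they ran from 1012 to 1421 in 129S1/SvImJ (1947), 3236 to 5211 in A/J (6188), 959 to 1334 in C57BL/6J (2003), 384 to 601 in BALB/cJ (966), 850 to 1056 in C3H/HeJ (1623), 193 to 220 in DBA/2J (389), 827 to 1784 in I/LnJ (1873), 338 to 506 in MRL/MpJ-Tnfrsf6lpr/J (911), 3216 to 3982 in NZB/BINJ (4992), 6 to 348 in SM/J (94), 1346 to 3195 in CAST/EiJ (3100) and 803 to 929 in PERA/Ei (1671). Strain on chow had 6686 to 8080 (8921), strain by diet 2157 to 4280 (4933) and strain by sex 928 to 1495 (2609). Lists had 15 to 18 for diet (18), 13 to 16 for sex by diet (20) and 19 to 22 for sex on chow (20), and list means 20 to 27 for strain by diet (26) and 5 to 12 for sex by diet (13).

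At adjusted p under 0.01, a stricter threshold, counts were 1709 in CAST/EiJ, 923 in PERA/Ei, 1101 in both 129S1/SvImJ and I/LnJ, 4023 in A/J, 1152 in C57BL/6J, 536 in BALB/cJ, 1010 in C3H/HeJ, 229 in DBA/2J, 493 in MRL/MpJ-Tnfrsf6lpr/J, 24 in SM/J, 177 for sex by diet and 1453 for strain by sex. With all probe sets, which are more than the genes, they were 14447 for diet, 9843 in females, 9208 in males, 10070 in A/J, 1421 in MRL/MpJ-Tnfrsf6lpr/J, 8295 in NZB/BINJ, 8703 for sex on chow, 7304 on high fat, 7824 for strain by diet and 15565 for strain on chow. Among genes above the median gene, fewer genes, 5398 passed for diet.

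With array quality weights counts were 2969 in PERA/Ei, 2584 in C3H/HeJ, 1069 in DBA/2J, 1580 in MRL/MpJ-Tnfrsf6lpr/J, 700 in SM/J, 967 for sex by diet, 7598 for strain by diet and 4118 for strain by sex. With each strain fitted alone, and so with fewer samples for the variance, 929 passed in 129S1/SvImJ, 1082 in C57BL/6J and 3 in SM/J. With strain as the unit (10 values per gene) limma gave 3443 for diet, 2962 in females, 2524 for sex on chow and 1655 on high fat. It gave 0 in males (4508 at unadjusted p under 0.05) and 0 for sex by diet (1507 at unadjusted p under 0.05). These fits kept the SM/J males, whose reversed change widens the spread between strains.

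With each array centred on its median 8920 passed in males and 8171 in NZB/BINJ. The rises and falls were 2211 and 6709 in males (2699 and 2953 as deposited), 2705 and 4675 in females (3107 and 2804), 155 and 427 for sex by diet (176 and 254), 1079 and 1123 in 129S1/SvImJ (1271 and 676), 2457 and 5576 in A/J (2836 and 3352), 950 and 1376 in C57BL/6J (1099 and 904), 869 and 895 in C3H/HeJ (1093 and 530), 991 and 1193 in I/LnJ (1150 and 723), 430 and 530 in MRL/MpJ-Tnfrsf6lpr/J (514 and 397), 2128 and 6043 in NZB/BINJ (2590 and 2402), 1452 and 2259 in CAST/EiJ (1649 and 1451) and 1057 and 760 in PERA/Ei (1212 and 459). After quantile normalization they were 213 and 188 for sex by diet, 1127 and 1021 in 129S1/SvImJ, 959 and 721 in C3H/HeJ, 222 and 160 in DBA/2J (265 and 124 as deposited), 2260 and 3370 in NZB/BINJ and 1054 and 653 in PERA/Ei.

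With an estimated correlation camera called 6 lists for diet, 2 for sex by diet and 6 for sex on chow, and fry called 8 for sex by diet. For sex by diet 280 genes passed without C3H/HeJ and 738 without SM/J. Without the 5 farthest libraries of the younger strains 268 passed within SM/J. Without male library 3 of CAST/EiJ on the atherogenic diet (without CAST male high-fat replicate 3) 2693 passed in CAST/EiJ and 1660 in PERA/Ei.

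In the fit without the SM/J males 268 genes passed within SM/J (20 shared with the 94), 700 for sex by diet (334 shared) and 1085 for strain by sex. Reversed were the sex by diet differences of the LXR targets (0.11), cholesterol synthesis (-0.0373) and endothelial markers (0.000314), and within SM/J, by females alone, Moxd1 (-0.0234), Fads1 (-1.10), Lyz2 (1.33) and Lyz1 (1.18).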

Other observations

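The list means of the older strains were compared within each strain as planned, and their pancreas markers and the setting without 1 library were looked at only after the values were seen.

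CAST/EiJ answered the diet with a strong macrophage and acute phase change. Its macrophage list rose by 1.77 (exact permutation p = 0.005), its acute phase list by 0.87 (exact permutation p = 0.005) and its matrix list by 0.50 (exact permutation p = 0.005). Among acute phase genes Saa1 rose by 4.58, Saa2 by 4.08 and Lcn2 by 4.01, and among fatty acid genes the thioesterase gene Acot1 by 2.84 and Pdk4, which spares glucose, by 2.68 (not past the threshold without replicate 3). Fabp4 rose by 2.18 and Plin2, a lipid droplet coat protein gene, by 1.04. Cholesterol synthesis fell by 1.41 and LXR targets rose by 1.10, each with exact permutation p = 0.005. Across genes the change had r = 0.726 with the mean change of the 10 younger strains.

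In PERA/Ei cholesterol synthesis fell by 0.85 and LXR targets rose by 1.10 (each exact permutation p = 0.005). Its macrophage list rose by 0.94 and its proliferation list by 0.41 (each exact permutation p = 0.005), with Ccnb2 at 1.24 (not past the threshold without replicate 3). Of the interferon genes Oas1a rose by 1.61 and Irf7 by 1.16, and the list did not pass (exact permutation p = 0.035, adjusted 0.0679). Cyp7a1, the rate-limiting hydroxylase of bile acid synthesis, rose by 1.39 (limma adjusted p = 0.019, not past the threshold without replicate 1 or 3), and Cyp2b10 fell by 1.83. Across genes the change had r = 0.782 with the younger strains.

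Male library 3 of CAST/EiJ on the atherogenic diet had a pancreas list mean 5.0 above that of its 2 partners. Without this library 2693 genes passed in CAST/EiJ in place of 3100, and whether the lost calls were pancreas genes was not tested.

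Among the 120 libraries of the 10 younger strains, the 2 farthest from their group means were labelled C57BL/6J male high-fat 3 and 2 (root mean square 0.215 and 0.214 log2 units), followed by library 2 of A/J male (0.193), A/J female (0.191) and NZB/BINJ male (0.185) on the same diet. On the list of male-biased genes, male library 1 of A/J on this diet lay 1.61 below its 2 partners.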
